A study of Mus musculus with 12 samples.

How the data were processed

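DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), in which genomic DNA is cut with a restriction enzyme to enrich CpG-rich fragments and treated with bisulfite so that unmethylated cytosines are read as thymine. The DNA came from splenic CD11c-positive dendritic cells of first-generation (F1) female C57BL/6 mice. Their mothers (F0) had received either corn oil or the plasticiser di(2-ethylhexyl) phthalate (DEHP) at 37 µg per kg per day for 10 days before mating with untreated males. The labels mark all 12 libraries as coming from mice immunised with OVA, and they place 6 libraries in the maternal corn oil group and 6 in the maternal DEHP group. They do not say whether each library came from a separate animal, and the extraction note names spleen tissue beside the dendritic cells.

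The deposited tables held no methylation level, read count or coverage for any single library. They held the authors' own comparison of the groups. One table listed every called site, and its hypermethylated and hypomethylated parts were deposited a second time. The parts added up to the whole table exactly, with no site in both. Per the file headers, each row gave a single position, a strand, a p-value, a q-value and a methylation difference in percentage points. Per the submitters' processing notes, methylKit was used and the genome build was GRCm38 (mm10). The aligner, the coverage minimum, the form of the test, the q-value method and the methylKit version are not given in the sources used here. In the deposited table the smallest absolute difference was 25.0 percentage points and the largest q-value was 3.62e-05, so the list had been restricted by the size of the difference. Of 2798 sites, 2073 had a deposited p-value of 0, and the smallest non-zero p-value was 1.11e-16. All sites were written on the plus strand, and no 2 of them were 1 bp apart. Which group was subtracted from which is not given in the sources used here. A positive difference, called hypermethylated in the deposited split, is read below as higher methylation in the maternal DEHP group.

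Because no value per library was used, no standard deviation, replicate check, leave-one-out fit, batch term or pairing could be computed, and the depth behind each site is unknown. The sample titles follow 2 numbering schemes, each with libraries of both groups, and whether these mark batches was not tested. The analysis below therefore describes the list of called sites and cannot test how the 12 libraries, or the mothers behind them, varied.

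Called sites within 1 kb of each other were merged into loci, since neighbouring CpGs are not independent. A locus took the direction of its mean difference, and its size was the mean absolute difference of its sites. Loci in each direction were compared by an exact two-sided binomial test. Sizes were compared by a two-sided permutation test of medians with 100000 resamples. Shares of loci inside annotated features were compared by Fisher's exact test. The directions of adjacent sites were compared with 100000 shuffles of the directions over all sites. The number of loci per chromosome was compared with 10000 draws in proportion to the number of protein-coding genes.

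Genes were taken from the RefSeq gene table of GRCm38.p6, which holds 49993 genes with coordinates, 21896 of them protein-coding. It gives gene spans without strand, exons or sequence. For this reason promoters, CpG density and the planned background of CpGs in in-silico MspI fragments could not be computed. They were replaced by windows reaching from 1000 bp outside to 100 bp inside either end of a gene span, and by random genes matched on biotype and on the decile of span length. A site was assigned to a gene if it lay in the span or within 5 kb on either side. These replacements were chosen after the gene table was seen. Gene-list counts were compared with 10000 matched random lists (two-sided), with Benjamini-Hochberg adjustment over 14 lists. The lists held 494 genes, of which 492 were in the gene table, and were fixed before the data were examined.

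The genes named were Ntf3, the 10 genes with the most called sites (ties in q-value broken by the size of the difference), the 6 largest gains and 6 largest losses in the gene-end windows of protein-coding genes other than predicted ones, and up to 4 members of each list by size. This rule was fixed at the same time, with promoters where the gene-end windows now stand. Ntrk2, Ntf5 and the homeobox genes named beyond 4 complete their lists and were added after their values were seen. Some genes that the rule takes are not reported here. Of the 141 sites that the rule takes, which include the nearest 2 to Ntf3 and leave out the sites of the genes added afterwards, 113 had a deposited q-value of 0 and the largest was 1.42e-06.

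The alternatives were a q-value under 0.001, a difference of at least 30 or 40 percentage points, single sites or a 10 kb merging distance, autosomes only, wider or protein-coding gene-end windows, other distances to genes and between neighbours, and, added after seeing the data, other expected chromosome shares, each shared site counted for 1 gene, and the exclusion of sites or loci of mixed direction. All tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The tests were also run on simulated data. The distance band for opposite directions was chosen after the data were seen, so its simulation was not a check made beforehand. With 89.9% of pairs opposite in the simulated data, all 50 simulations were called for the directions of adjacent sites, against 2.0% of 50 without a planted effect. The planted share is close to the one observed, so how weaker patterns would be called is not known from it. Of 100 simulated lists of 40 genes with 10 added hits 100% were called, and of 100 random lists 0% were. The random lists were drawn from protein-coding genes without regard to CpG content, and smaller excesses were not simulated. How the list test behaves for CpG-rich genes or for small excesses is therefore not known from these simulations. Intervals are 95% exact (Clopper-Pearson) and treat loci or pairs as independent.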

Results

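Methylation was compared between splenic dendritic cells of female offspring whose mothers had received DEHP (6 libraries) or corn oil (6 libraries). The comparison asks whether exposure of the mother to a phthalate changes DNA methylation in the antigen-presenting cells of her offspring. The series title puts the neurotrophin gene Ntf3 forward as a marker of allergic disease. The values came from the authors' deposited table of called sites, so a difference is that between the groups as wholes, without a spread between libraries, and the read depth behind it is unknown. The mothers received the treatment, and how many mothers or litters the libraries represent is not known here. The deposited p-values can therefore not be read as measured against the variation between mothers. Directions rest on reading a positive difference as higher methylation in the maternal DEHP group, which the table itself does not state.

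The authors' deposited table held 2798 differentially methylated CpG sites, 1354 hypermethylated and 1444 hypomethylated in the maternal DEHP group. The median difference was 28.8 percentage points among the hypermethylated sites and -28.7 among the hypomethylated sites. The largest gain was 58.5 points, beside Col9a2, and the largest loss was -56.9 points, beside Ercc6l on the X chromosome. Most differences lay close to the minimum of the list. Of all sites, 1696 (60.6%) differed by less than 30 points and 152 by 40 points or more. Merging sites within 1 kb gave 2284 loci, of which 1928 were single sites. Of these loci, 1126 gained and 1158 lost methylation, a share of 49.3% gaining (95% interval 47.2 to 51.4), which was not distinguishable from an even split (exact binomial test, p = 0.517). Gaining and losing loci had median sizes of 28.8 and 28.7 percentage points, a difference of 0.08 points (two-sided permutation test, p = 0.73).

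Ntf3, which encodes neurotrophin-3, carried no called site. The deposited table lists only sites past a minimum difference, and which CpGs at Ntf3 were covered is unknown. A smaller change at Ntf3, or a lack of coverage there, would also leave no called site. The absence is therefore not evidence that methylation at Ntf3 was unchanged. The span of Ntf3 on chromosome 6 runs from 126101412 to 126166772 (GRCm38). The nearest site in the authors' deposited table lay at position 126196296, 29.5 kb beyond the end of the span and within no annotated gene, and it was hypomethylated by -29.3 percentage points (deposited q-value of 0). It was the only called site within 50 kb of Ntf3. The next site on the chromosome lay 758 kb from Ntf3, in Scnn1a, and was hypermethylated by 25.8 points. Of the 25 neurotrophin and receptor genes, 6 carried a called site in their span or within 5 kb, against 2.34 expected from length-matched genes (permutation p = 0.044, adjusted p = 0.308 over 14 lists), so the excess did not pass the correction. Bdnf, a second neurotrophin, held sites of opposite direction at 109677375 (30.6 points) and 109677413 (-33.2 points) on chromosome 2. Sorl1 and Ntrk2, a sorting receptor and the receptor of BDNF, each held 1 hypomethylated site in the authors' deposited table (-31.1 and -27.3 points). Sorcs2 held 2 hypomethylated sites, the larger at -32.5 points, and 1 hypermethylated site (26.8 points). A site near Ntf5 was hypomethylated by -25.1 points.

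The genes with the most called sites were a ribosomal DNA copy, an X-linked gene and an imprinted locus. At the Snrpn and Snurf genes, an imprinted locus on chromosome 7, 9 of 9 sites between 60005111 and 60005199 were hypermethylated, by 41.4 to 56.6 percentage points (mean 46.0) in the authors' deposited table. These sites also lie in the span of the long noncoding RNA gene Snhg14. At Gnas, an imprinted locus on chromosome 2 with an antisense transcript, Gnasas1, 5 of 5 sites between 174285639 and 174285711 were hypomethylated, by -28.7 to -36.9 points, and a sixth site at 174300469 was hypermethylated by 35.2 points. Sox3, an X-linked transcription factor gene, held 13 sites between 60892512 and 60892659, all hypomethylated, by -25.0 to -45.8 points (mean -38.4). The noncoding gene Gm38438 is named by the same sites, which lie within 5 kb of it. In the ribosomal DNA copy on chromosome 17, near Rn18s-rs5 and AY036118, the authors' deposited table held 23 sites, 12 hypermethylated and 11 hypomethylated. Reads from the many ribosomal copies cannot be told apart, so these values do not belong to 1 place. Meioc, a meiosis gene on chromosome 11, held 6 hypermethylated sites and 1 hypomethylated site, from -26.6 to 37.7 points. Camta1, a transcription activator gene on chromosome 4, held 6 hypomethylated sites and 1 hypermethylated site, from -33.1 to 26.5 points. The Camta1 sites were spread from 151262562 to 151659422 and do not form a single run. The predicted gene Gm9257 on chromosome 12 held 5 hypermethylated sites and 1 hypomethylated site. Of the 15 loci with at least 4 sites and a single direction, 5 lay on the X chromosome or at imprinted genes, and 2 of these were other than Snrpn, Gnas and Sox3.

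**Figure D1:**
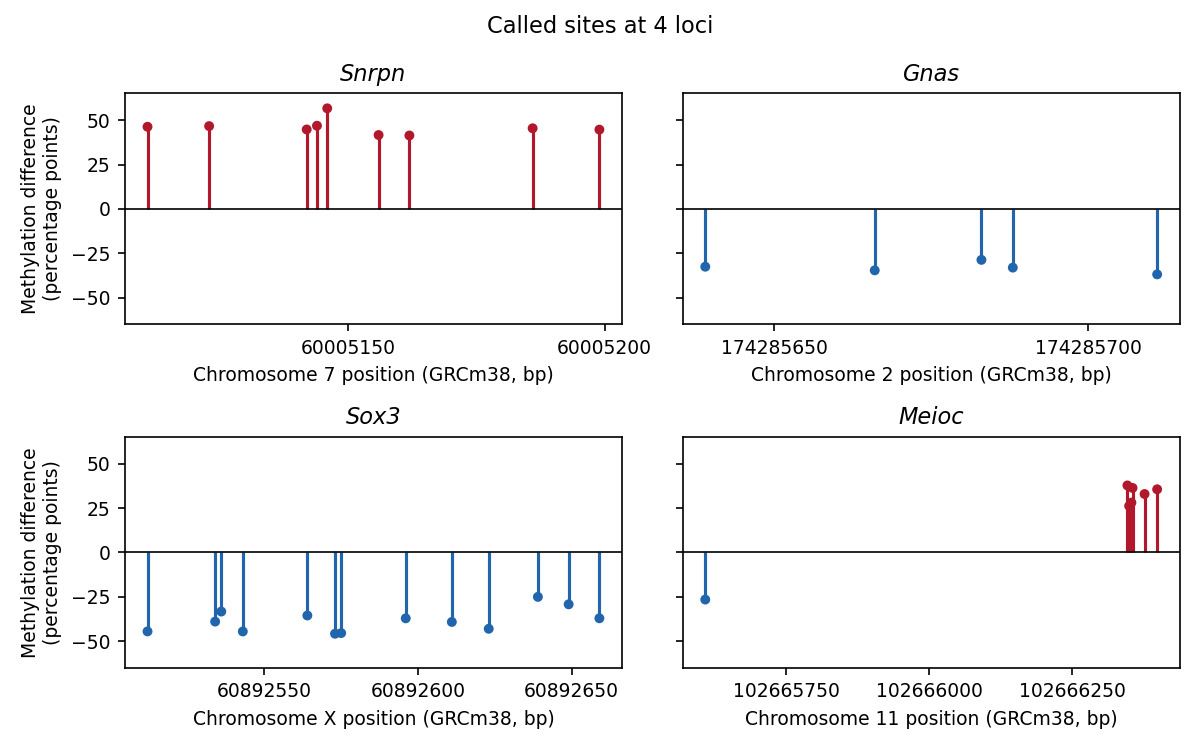
Methylation difference in percentage points (vertical axis, positive values hypermethylated in the maternal DEHP group) of each called site against its GRCm38 position (horizontal axis) at 4 loci; each line with a point is 1 site, and the values have no error because they are the deposited group differences. The 9 Snrpn sites lie between 41.4 and 56.6, the 5 Gnas sites and the 13 Sox3 sites are all below 0, and Meioc has 6 sites above 0 and 1 below.

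At the ends of protein-coding gene spans, the authors' deposited table placed the largest gains at Col9a2 (58.5 percentage points, 213 bp outside the span), Snurf (56.6 points), Noxa1 (46.3 points), Macf1 (43.3 points), Prag1 (43.0 points) and Tcl1 (42.8 points). Within the span of Col9a2 lay called sites of the other direction, at 121045951 (-30.8 points) and 121052557 (-27.4 points). Col9a2 encodes a chain of a cartilage collagen, Noxa1 an activator of NADPH oxidase and Macf1 a cytoskeletal crosslinker. Among the largest losses in the authors' deposited table were those at Ercc6l (-56.9 points, 24 bp outside the span), Npr2 (-41.7 points), Cd200r2 (-38.9 points), Kbtbd13 (-38.3 points) and Cblc (-37.8 points). Npr2 encodes a natriuretic peptide receptor, and Cd200r2 belongs to the CD200 receptor family. In all, 109 protein-coding genes other than predicted ones had a called site in such a window. Of gaining loci, 7.90% lay in a gene-end window of a protein-coding or long noncoding gene, and of losing loci 6.99% (Fisher's exact test, p = 0.426). Protein-coding gene spans held 48.8% of gaining and 50.9% of losing loci (Fisher's exact test, p = 0.316).

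Of the 14 gene lists, the homeobox and patterning transcription factors were the one that carried called sites more often than length-matched genes. Of 94 members, 14 had a called site, against 4.87 expected (permutation test, adjusted p = 0.0112), 7 with gains alone and 7 with losses alone. Besides Sox3, the authors' deposited table had gains at the limb and heart factor gene Tbx3 (41.9 percentage points) and at Hoxb3 (34.2 points), and losses beside the neural factor gene Sox1 (-35.2 and -29.5 points). The others were Gbx2, Foxd3, Hoxd13, Pax7 and Otx1, with gains, and Hoxd3, Hoxd4, Hoxa9, Hoxa10 and Pitx1, with losses. Hoxa9 and Hoxa10 shared 1 site, as did Hoxd3 and Hoxd4, and with each such site counted for 1 gene the list no longer passed (permutation test, adjusted p = 0.0644). It did not pass within gene spans alone either (permutation test, adjusted p = 0.0868), and over all settings the adjusted p ran from 0.0028 to 1. Whether the CpG-rich sequence that RRBS favours is more frequent at these genes was not part of the comparison.

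Lists of dendritic cell and allergy genes did not pass the test against length-matched genes. Of 30 genes of conventional dendritic cell identity, 1 carried a called site (2.09 expected, permutation test, adjusted p = 1), the adhesion gene Cadm1 (-25.8 percentage points). Of 36 genes of the type 2 and allergic cytokine axis, 3 did (2.18 expected, permutation test, adjusted p = 1). In the authors' deposited table, Il13ra1, an X-linked receptor gene for interleukin-13, had 3 hypomethylated sites (-26.6 to -35.8 points), while Jak1 had a gain of 36.05 points and the T helper 2 factor gene Gata3 a gain of 25.9 points. Among 37 genes of dendritic cell activation, 2 carried sites (2.11 expected, permutation test, adjusted p = 1), namely Tgfb2 (-27.5 points) and the costimulatory gene Cd80 (26.8 and -25.2 points). Among 29 interferon genes, 1 did (1.44 expected, permutation test, adjusted p = 1), namely Oasl1, with a loss of -38.4 points in the authors' deposited table.

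Nuclear receptors and other genes linked to phthalates carried sites at 6 of 40 members (3.62 expected, permutation test, adjusted p = 0.960). The authors' deposited table had gains within Ppara (29.6 percentage points) and Ppard (30.3 points), which encode the peroxisome proliferator-activated receptors alpha and delta, and within Esrrb (36.9 points). Of 50 DNA methylation and chromatin regulators, 5 carried sites (4.36 expected, permutation test, adjusted p = 1). Prdm16 held 4 hypomethylated sites and 1 hypermethylated site, and the Polycomb gene Suz12 held 1 of each (34.2 and -25.2 points). Ehmt1 and Hdac9 held 1 site each (29.7 and -27.7 points) in the authors' deposited table. Of 47 imprinted genes, 4 carried sites (3.65 expected, permutation test, adjusted p = 1). Besides Snrpn and Gnas these were Kcnq1 (-28.2 points) and Dlk1 (27.1 points, 3838 bp from the span).

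Marker genes of other cells that a splenic CD11c preparation could hold were tested in the same way. The expected counts were only 0.793 to 1.98 genes per list, so only a large excess could pass. Whether the mixture of cells differed between the groups was not tested and cannot be read from these counts. Called sites lay at 3 of 20 B cell markers (1.46 expected, permutation test, adjusted p = 0.960), namely Spib (26.8 percentage points), Cd22 (-25.9 points) and Cxcr5 (25.3 points). They lay at 2 of 30 T and NK cell markers (1.98 expected, permutation test, adjusted p = 1), with Prf1 at -33.8 points and Tbx21 at 27.2 points in the authors' deposited table. They lay at 1 of 30 macrophage, monocyte and neutrophil markers (Elane, -26.1 points, 1.53 expected) and at 1 of 14 erythroid markers (Ank1, 26.6 points, 0.793 expected), both with a permutation adjusted p of 1. Of 12 plasmacytoid dendritic cell markers 3 carried sites (0.899 expected, permutation test, adjusted p = 0.460), namely Tcf4 (from -28.5 to 28.2 points), Runx2 (-28.0 points) and Spib, which is also a B cell marker.

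The X chromosome held more called loci than any autosome in proportion to its genes. It carried 169 loci against 102 expected from its 966 protein-coding genes, 1.66 times the expected number (exact binomial test, adjusted p = 7.32e-09 over 20 chromosomes). Of the X-linked loci 80 gained and 89 lost methylation, a share of 47.3% gaining (95% interval 39.6 to 55.1), which was not distinguishable from the 49.5% on autosomes (Fisher's exact test, p = 0.632). By the same exact test, chromosome 12 had 1.45 times (104 loci, adjusted p = 0.0016) and chromosome 5 had 1.30 times the expected number (174 loci, adjusted p = 0.00294). Chromosome 15 had 1.29 times (106 loci, adjusted p = 0.0237) and chromosome 4 had 1.28 times (180 loci, adjusted p = 0.0031), also by the exact binomial test. Chromosome 7 had 0.68 times (146 loci, exact binomial test, adjusted p = 3.25e-06), and 0.80 times with olfactory and vomeronasal receptor genes left out of the expectation (adjusted p = 0.0213). Chromosomes 19, 6 and 11 had 0.73, 0.77 and 0.79 times the expected number (exact binomial tests, adjusted p = 0.0344, 0.0235 and 0.0119). Without the receptor genes in the expectation, chromosome 15 (1.22 times, adjusted p = 0.0946) and chromosome 19 (0.743 times, adjusted p = 0.0677) no longer passed the exact binomial test, and the other chromosomes named here did. The distribution over the chromosomes differed from that of the genes (chi-square of 146, permutation p = 0.0001, the smallest that 10000 draws can give). Among sites that differed by at least 40 points the X chromosome had 1.33 times the expected loci, which did not pass (exact binomial p = 0.400). The number of CpGs that could be tested on each chromosome was not part of this expectation. On chromosome 12, every locus with at least 4 sites lay between 19606445 and 23634618 and held sites of both directions. Among them were those at the predicted genes Gm9257, Gm3993, Gm10479 and Gm40862. Whether reads of repeated copies contribute to these loci or to the chromosome 12 excess was not tested.

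**Figure D2:**
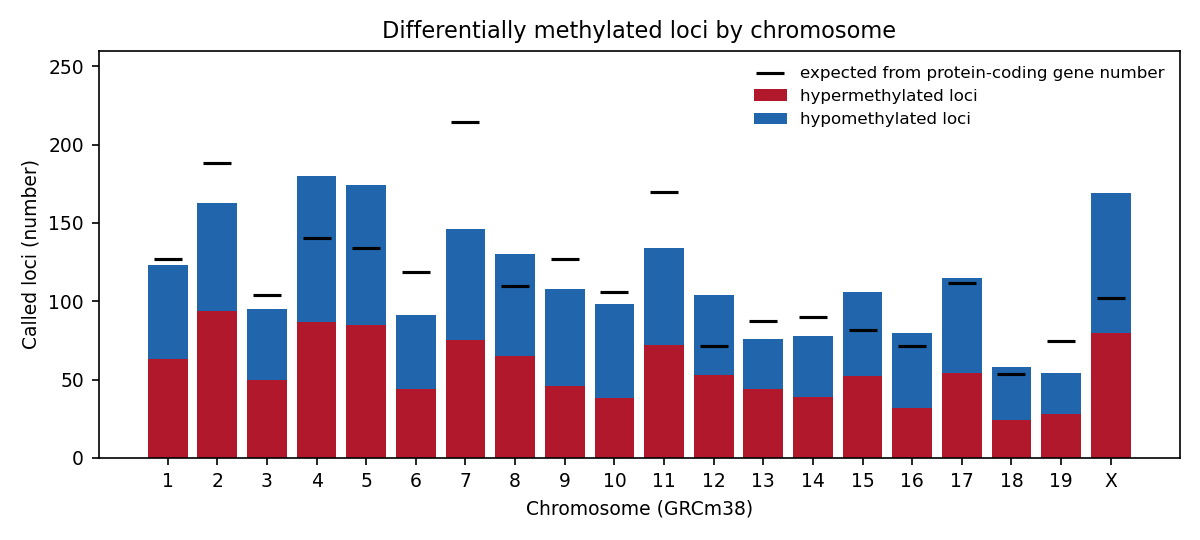
Number of called loci (vertical axis) on each GRCm38 chromosome (horizontal axis), stacked as hypermethylated (red) and hypomethylated (blue) in the maternal DEHP group; black dashes mark the number expected from protein-coding genes. The X chromosome bar, 169 loci, stands above its dash at 102, with 80 hypermethylated and 89 hypomethylated.

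Adjacent called sites mostly went in the same direction within 100 bp and mostly in opposite directions at 110 to 180 bp. Within 10 bp, 90 of 92 adjacent pairs had the same direction (97.8%, 95% interval 92.4 to 99.7), and within 100 bp 294 of 336 did (87.5%, 83.5 to 90.8). Between 110 and 180 bp, 118 of 132 pairs were opposite (89.4%, 95% interval 82.8 to 94.1), for example the 2 sites of Suz12 and 2 of the sites of Tcf4. After shuffling, 50.03% and 50.05% of the pairs within 10 and 100 bp had the same direction, and for each of the 3 distances the permutation p was 1e-05, the smallest that 100000 shuffles can give. Beyond 180 bp and up to 1 kb, 24 of 36 pairs were opposite (66.7%, permutation p = 0.066). In steps of 20 bp from 180 to 240 bp, 2 of 4, 1 of 3 and 2 of 3 pairs were opposite. The next steps held 5 of 5 at 240 to 260 bp and 4 of 4 at 260 to 280 bp. With so few pairs, the values do not show whether the pattern ends at 180 bp. At 1 to 10 kb, 22 of 45 pairs were opposite (48.9%, permutation p = 1). Over all adjacent pairs within 1 kb, 63.6% had the same direction (327 of 514, permutation p = 1e-05). The band from 110 to 180 bp was chosen after the data were seen.

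**Figure D3:**
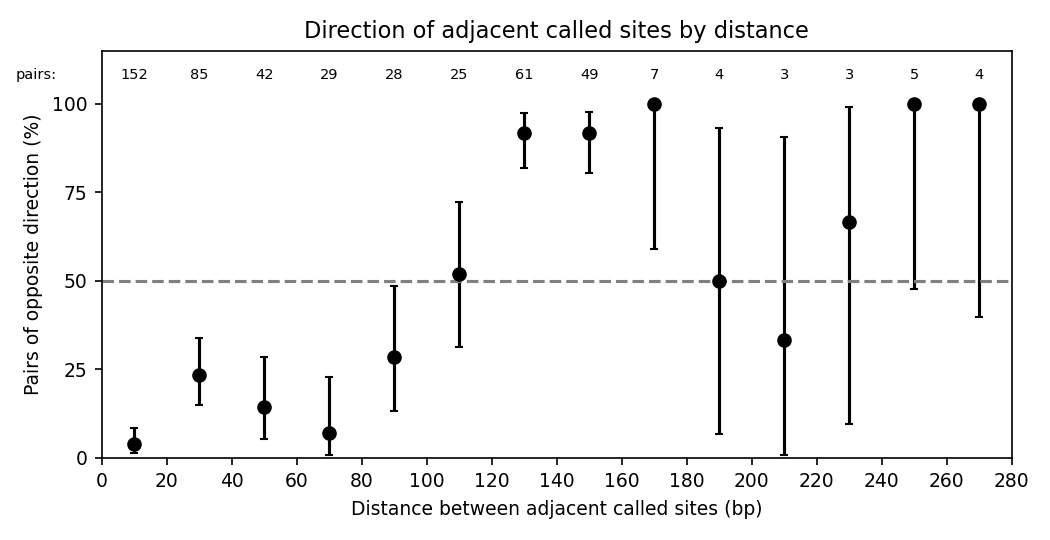
Percent of adjacent called sites that differ in opposite directions (vertical axis) by the distance between them in steps of 20 bp (horizontal axis); points are shares, bars are 95% exact intervals, the numbers on top are pairs, and the dashed line marks 50%. Pairs up to 20 bp apart are opposite in 3.9% of cases, and pairs 120 to 160 bp apart in about 91.8%.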

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

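The band of 110 to 180 bp and the settings without opposite pairs or mixed loci, with shared sites counted once and with other expected chromosome shares were chosen after seeing the data. No result turned its direction while past a threshold. A q-value under 0.001 removed no site and so tested nothing. With a difference of at least 30 percentage points, 550 hypermethylated and 552 hypomethylated sites were left, and with at least 40 points 80 and 72. At 30 and 40 points, within gene spans alone, and with each shared site counted for 1 gene, 0 gene lists passed in place of 1. The homeobox list then had 2.24, 6.24, 2.87 and 2.51 times the expected number of genes, with adjusted p of 1, 1, 0.0868 and 0.0644 in permutation tests. Fewer sites were tested in the first pair of these, the last left out Hoxa10 and Hoxd4, and for gene spans the cause was not tested. The list passed with 20 kb around genes and without the opposite pairs (permutation tests, adjusted p = 0.0028 and 0.0084). The X chromosome held 1.33 times the expected loci at 40 points, which no longer passed (exact binomial p = 0.400, with fewer loci), against 1.46 to 1.68 times under the other settings that changed the sites or the expected number. Opposite pairs between 110 and 180 bp fell to 78.9% at 30 points and were too few to test at 40 points. In no setting run did gaining and losing loci differ past the threshold in number, size or share in gene spans and gene ends. The gene-end share of gaining loci exceeded that of losing loci by 0.91 percentage points in the main setting. It did so by 2.50 at 30 points and 5.11 at 40 points (Fisher's exact tests, p = 0.188 and 0.371). The size gap rose from 0.08 to 1.33 points at 40 points (two-sided permutation test, p = 0.115). With fewer loci left, these tests cannot show that the shares and sizes stayed alike. The Ntf3 neighbour (-29.3 points) is below the 30-point minimum. Promoter shares, CpG density, the in-silico RRBS background, leaving out libraries and a term for the title series were planned and not run, because strand, sequence and values per library were not in the material used here. No paired analysis was possible because the tables carry no values per library. Depth is unknown, so no difference can be graded by its coverage, and the deposited p-values of 0 carry no ranking.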

Other observations

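All patterns, loci and tests in this part were chosen after the data were seen, the band of 110 to 180 bp included. For the tests on autosomes, on repeated copies and on gene families, what each explanation predicts was written down before that test was run.

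Further one-direction runs in the authors' deposited table lay in genes outside the fixed lists. Bsn, which encodes the presynaptic scaffold bassoon, had 6 hypomethylated sites within 89 bp on chromosome 9 (-25.5 to -36.0 percentage points), and the X-linked gene Shroom2 had 6 hypomethylated sites within 158 bp (-25.9 to -35.2 points). Oprd1, the delta opioid receptor gene, and Chst5, a sulfotransferase gene, had 4 and 5 hypomethylated sites. Fbxo31, an F-box gene on chromosome 8, had 6 hypermethylated sites (25.3 to 46.2 points), Lingo3 on chromosome 10 had 5 (33.4 to 42.8 points) and the X-linked gene Tceanc had 4 (25.8 to 36.7 points). The longest run outside any annotated gene held 15 hypomethylated sites between 3083519 and 3083723 on chromosome 19 (-25.5 to -33.4 points). Among 24 loci with at least 4 sites, 15 had a single direction, 5 of them gaining and 10 losing. Gene families were also compared by the stem of their symbols. Of 102 families with at least 20 protein-coding genes, 0 carried called sites more often than length-matched genes after adjustment; the excess with the smallest p was that of the stem Dusp, dual-specificity phosphatases, with 5 of 24 genes against 1.22 expected (permutation p = 0.0126, adjusted p = 0.428), and olfactory receptors had 7 of 1110 against 17.1 expected (adjusted p = 0.184).

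Sites 110 to 180 bp apart that change in opposite directions are not what a shared gain or loss of methylation over a region would give. Chance directions are excluded, since 89.4% of the 132 pairs were opposite against 49.96% after shuffling (permutation p = 1e-05), and X inactivation is excluded as the cause, since 88.9% of 126 pairs on autosomes were opposite. A candidate explanation is that the 2 ends of a size-selected fragment were represented unequally in the groups, for example through reads from one strand or one end. The sizes of the partners differed by a median of 3.31 points against 4.17 points for re-drawn partners (one-sided permutation p = 0.0201, 118 pairs). The candidate explanation predicts such a smaller gap, but so would any cause that acts alike on both sites of a pair. This size test therefore cannot decide between causes. The gain came first in 52 and second in 66 pairs (exact binomial p = 0.231). Reads of repeated copies placed at one position stay open, because 49.2% of opposite pairs and 49.95% of other loci lay in protein-coding gene spans (Fisher's exact p = 0.925), and an effect of maternal DEHP on such pairs was not tested, as neither strand nor library values were used here; without these pairs, 8.43% of the sites, the list held 1236 hypermethylated and 1326 hypomethylated sites.

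Some long one-direction runs lay on the X chromosome or at imprinted genes, where 1 of 2 alleles can be methylated. The X-linked loci were grouped by chromosome alone, and whether 1 allele is methylated at these sites was not measured. Of the 15 one-direction loci with at least 4 sites, 5 (33.3%) were on the X chromosome or at imprinted genes, against 7.45% of the other loci (Fisher's exact p = 0.00388), but this grouping was formed after the runs at Snrpn, Gnas and Sox3 were seen. Without these 3 loci it was 2 of 12 (16.7%, Fisher's exact p = 0.226), so the data do not decide whether such loci hold more runs. Unequal sampling of the methylated and the unmethylated allele, as from few cells or strong amplification, may give such runs in either direction, and Snrpn gained while Gnas and Sox3 lost methylation. A change of imprinting or of X inactivation with maternal DEHP would give the same runs and was not tested, and the 10 other runs lie elsewhere.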
